A study of Mus musculus with 4 samples.

How the data were processed

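The samples were 4 poly(A) RNA-seq libraries of mouse embryonic stem cells of the 129SvEv background with floxed Smarca4, 2 from cells given ethanol and 2 from cells given 4-hydroxytamoxifen. All 4 carry the same genotype label, so the groups were taken from the titles and the treatment labels. The values were counts of reads per gene symbol, as the authors deposited them, with 5 closing summary lines in the form that HTSeq writes. Per the submitters' processing notes, the tools were CASAVA 1.8.2, Bowtie 1.1.1, HTSeq and DESeq2 and the genome build was mm9; the role of each tool, the gene annotation and the strand setting are not given in the sources used here. Without a stated strand setting, reads from overlapping or antisense genes cannot be told apart, and reads of near-identical copies may have been split or dropped. The counts were used as deposited, and the summary lines stayed out of library sizes and tests.

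Reads in genes numbered 16130823 and 27086142 in ethanol replicates 1 and 2 and 13458463 and 17191445 in tamoxifen replicates 1 and 2. Reads assigned to no gene made up 51.7, 40.8, 37.6 and 35.0% of all counted reads in that order, and the ribosomal RNA precursor Rn45s took 0.391, 0.299, 0.653 and 0.691% of the reads in genes. Counts of the replicates of a group differed by more than sampling noise (chi-square per degree of freedom 39.6 for ethanol and 11.1 for tamoxifen), so no library was counted as a duplicate. Of 24428 genes, 4610 had no read and 14479 passed the filter on low counts. The biological coefficient of variation was 12.6%, and the first principal component held 79.3% of the variance.

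Tamoxifen was compared with ethanol with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (robust, TMM factors, filterByExpr, group as the only term), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Positive log2 fold changes mean higher with tamoxifen, and standard errors were taken as the absolute log2 fold change over the square root of F. Levels are TMM-normalised CPM (counts scaled to a common library size) computed from the deposited counts. Gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and again with an estimated correlation, and with fry; adjusted p-values of lists were corrected over the 32 lists tested. Of the 33 lists fixed, the mitochondrially encoded transcripts had 0 genes in the files. With an estimated correlation no camera call held, with or without GC correction. That form of the test rests on 2 residual degrees of freedom and has little power here. It dropped even the LIF list, whose estimate (-0.0107) lay below the preset 0.01. A call lost in it therefore does not by itself show that correlated members made the call. The preset calls in turn rest on the assumed correlation. Taken for 1 direction, fry called the Polycomb and cholesterol lists without GC correction, the p53 targets with it, and no other list in either.

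The test, the lists, the rule for named genes and the alternatives without GC correction were fixed before the data were examined. The rule took Smarca4, the 10 largest increases and the 10 largest decreases among called genes with a mean log2 CPM of at least 2 and both tamoxifen libraries on 1 side of both ethanol libraries, up to 4 members of each list with the smallest adjusted p, and Pou5f1, Sox2, Nanog, Klf4, Esrrb and Smarca2. Clone names were skipped among the largest changes, which left out 1 gene, and 3 genes that the rule took from the lists are not reported here. The alternatives were other scaling (RLE, upper quartile, total counts), other filters, DESeq2 1.42.0, limma voom, the replicate number as a block, other thresholds and leaving out each library. Where a library is left out, the lone library of its group is assumed to vary like the other group.

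GC correction was added after seeing the data. For each library the deviation of log2 CPM from the gene's mean was fitted against transcript GC content by loess (span 0.5, degree 1) and entered as an offset. GC content and length came from GENCODE transcripts of GRCm38, used only for these values, gene names, chromosome names and the order of genes; of 24428 symbols, 23535 matched directly, 524 through a synonym and 369 not at all, and 99.4% of tested genes had a value. No coordinates are given, since the build differs from that of the files.

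The procedure was tested on simulated data for this comparison, with 200 of the 14479 genes changed. The changed genes were drawn only from genes above a limit of mean log2 CPM, so recovery of the lowest genes was not tested. In the real data 44.5% of tested genes were called, far more than were changed here, so these shares need not hold there. The procedure recovered 23.9% of 1.5-fold, 88.1% of 2-fold and 100% of 4-fold changes. It called 14 of 14279 unchanged genes, 9.03% of its calls and above the 5% aimed at. With a GC trend added to the simulated tamoxifen libraries it called 4265 unchanged genes without correction and 18 with correction, where it recovered 17.9, 79.1 and 98.5% of the 1.5-, 2- and 4-fold changes and the unchanged genes were 12.2% of its calls. The added trend was linear, equal in both tamoxifen libraries and absent from ethanol, whereas the real ethanol libraries also differed along GC content. The simulation thus does not show that corrected calls in the real data are right. A list shifted by 0.5 log2 was called by camera at the preset correlation (camera adjusted p = 4.27e-28) and missed with an estimated correlation (adjusted p = 0.471).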

Results

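The data were poly(A) RNA-seq gene counts from mouse embryonic stem cells in which both copies of Smarca4 carry loxP sites and a tamoxifen-activated Cre recombinase can remove the flanked part. Smarca4 encodes BRG1, a catalytic ATPase of the BAF (mSWI/SNF) chromatin remodeling complexes. Cells were grown in serum and LIF, the cytokine that maintains mouse stem cells, and were given ethanol (n = 2) or 0.8 uM 4-hydroxytamoxifen (n = 2) for 48 h and collected 72 h after the start. The ethanol libraries held 16130823 and 27086142 reads in genes and the tamoxifen libraries 13458463 and 17191445. A tamoxifen-treated culture without the loxP sites was not analysed here, so each difference is that between the treatments, with deletion, drug and active Cre together. The labels do not say that the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

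The comparison asks which transcripts change after acute loss of Smarca4. Smarca4 itself fell 5.38-fold, from 369 ± 56.9 to 68.6 ± 0.152 CPM (counts scaled to a common library size; SD, n = 2), with counts of 5042 and 10649 in the ethanol libraries and 968 and 1226 in the tamoxifen libraries. Its log2 fold change was -2.43 ± 0.17 (SE; edgeR quasi-likelihood test, adjusted p = 1.08e-05), leaving 18.6% of the ethanol level (14.8 to 23.4% for 2 SE either way). The gene-level count includes exons outside the deleted part, so the remaining reads do not measure intact transcript. Smarca2, which encodes the alternative ATPase BRM, had a log2 fold change of 0.45 ± 0.17 (edgeR quasi-likelihood test, adjusted p = 0.0499), a call at the threshold that was lost with GC correction (0.37), with DESeq2 (0.45), without ethanol replicate 2 (0.27), without tamoxifen replicate 1 (0.44) and without tamoxifen replicate 2 (0.47).

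**Figure D1:**
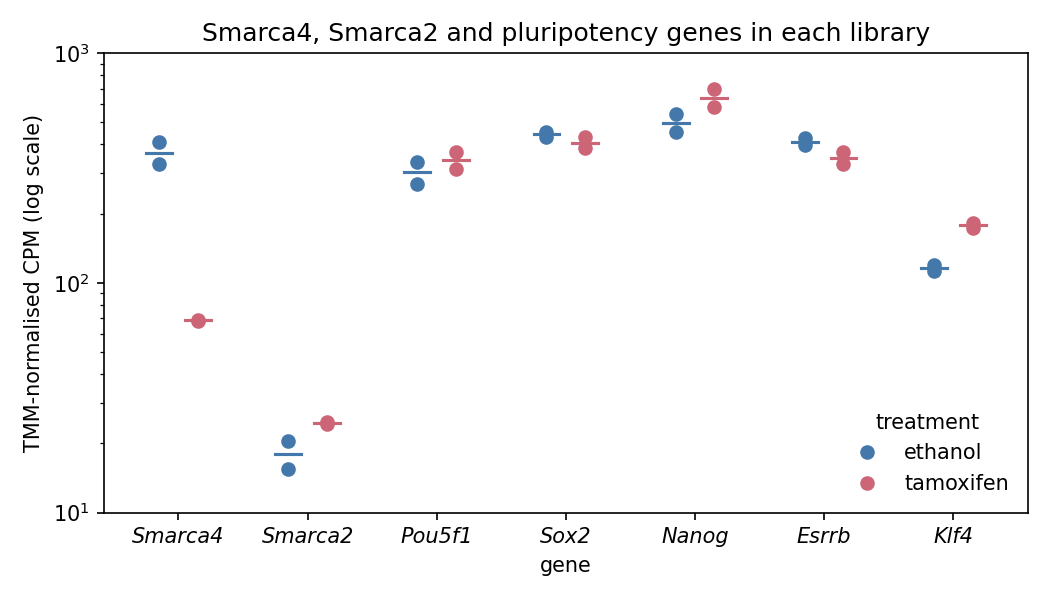
TMM-normalised CPM (log axis) of Smarca4, Smarca2 and 5 pluripotency genes in each library, with points for the libraries and a line at each group's mean (n = 2 ethanol, n = 2 tamoxifen). Smarca4 lies at 369 CPM on average with ethanol and 68.6 with tamoxifen, while Pou5f1 and Sox2 lie between 269 and 454 CPM in the 4 libraries.

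Among genes with a mean log2 CPM of at least 2, the largest increase was that of Lix1, which rose 9.58-fold, from 0.842 ± 0.376 to 7.63 ± 0.412 CPM (SD, n = 2), and Ccno, a cyclin of multiciliated cells, rose 9.55-fold. The transcription factors Tbx4 (2.31 ± 0.28 log2, SE) and Dmrt3 (2.06 ± 0.28), the secreted Nodal antagonist Cer1 (2.06 ± 0.25), the WNT receptor Fzd2 (1.93 ± 0.19), the semaphorin Sema3e (2.0 ± 0.22), the claudin Cldn3 (1.99 ± 0.22), the matrix protein gene Emilin1 (2.05 ± 0.23) and Zfp771 (1.88 ± 0.21) completed the 10 largest increases. Sema3e was the most abundant of them, at 141 ± 1.07 CPM with tamoxifen. All 10 remained called with GC correction, with smaller log2 fold changes for Dmrt3 (1.43), Emilin1 (1.31), Cldn3 (1.20) and Zfp771 (0.80; 0.61 and not called when tamoxifen replicate 2 was also left out). The uncorrected value of Ccno was 4.22 without ethanol replicate 1 and 2.49 without ethanol replicate 2.

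At the same level limit, the largest decrease was that of Dpys, the pyrimidine-degrading dihydropyrimidinase, which fell 13.7-fold, from 11.7 ± 0.805 to 0.874 ± 0.365 CPM (SD, n = 2). Lrrc34 (-3.24 ± 0.18 log2, SE) and Lrriq4 (-3.11 ± 0.27), which lie next to each other on chromosome 3, both fell, as did the microtubule-associated Mtap7d3 (-3.19 ± 0.19), the G protein subunit gene Gna14 (-3.08 ± 0.25), the endophilin gene Sh3gl2 (-3.03 ± 0.24) and Nhs (-2.70 ± 0.17). Rpl22l1, a paralog of the ribosomal protein gene Rpl22, fell 6.08-fold, the signal transducer Stat4 fell 5.99-fold, and Trh, the thyrotropin-releasing hormone gene, went from 69.2 ± 21.8 to 12.3 ± 0.784 CPM. All 10 remained called with GC correction and, uncorrected, without any 1 library, and Lrrc34 was at -2.65 after the correction. With GC correction Rpl22l1 was not called without tamoxifen replicate 1 (-2.24) or tamoxifen replicate 2 (-2.12).

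Over all genes, 6441 of 14479 tested (44.5%) differed between the treatments, 3119 higher and 3322 lower with tamoxifen (edgeR quasi-likelihood test, adjusted p under 0.05). Of these, 859 rose and 970 fell at least 2-fold. Both tamoxifen libraries lay on 1 side of both ethanol libraries for 74.0% of all tested genes, where chance gives 33.3% for a single gene. Genes are not independent, so any library-wide difference between the groups, also a technical one, can separate many at once. With total counts in place of TMM factors, 4082 genes were higher and 2520 lower, and the median log2 fold change of all genes was 0.12 in place of -0.01. These 4082 genes were 61.8% of the calls, against 48.4% with TMM. Fewer genes were called when either tamoxifen library was left out. The ethanol pair alone then set the spread, and it differed more (chi-square per degree of freedom 39.6, against 11.1 for tamoxifen).

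Genes rich in G and C were higher with tamoxifen and genes poor in them lower. In the tenth of genes with the lowest GC content of the transcript (31.0 to 41.5%), the median log2 fold change was -0.72, with 26 genes higher and 1002 lower, and in the tenth with the highest (58.1 to 79.0%) it was 0.69, with 845 higher and 27 lower. The Spearman correlation of log2 fold change with GC content was 0.633 across genes, which are not independent replicates. The 2 ethanol libraries also differed along GC content, with a correlation of -0.253 for replicate 2 against replicate 1. A test with each library's GC trend removed, chosen after seeing the data, called 2977 genes (1435 higher, 1542 lower). Of the 6441 genes, 2185 (33.9%) were called in the same direction in both tests and 5 in opposite directions. Among the 1829 genes changed at least 2-fold, 1174 (64.2%) were called in both. With the correction, 1300 genes were called without tamoxifen replicate 1 and 812 without tamoxifen replicate 2. Of 107 genes chosen by the naming rule and called with the correction, more lost the call without a tamoxifen library than without an ethanol library. Genes of that rule that gained a corrected call did so mostly without an ethanol library. Not every such loss or gain is printed with its gene. The corrected value is therefore given wherever it ended a call or moved a fold by over 1.5 times.

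**Figure D2:**
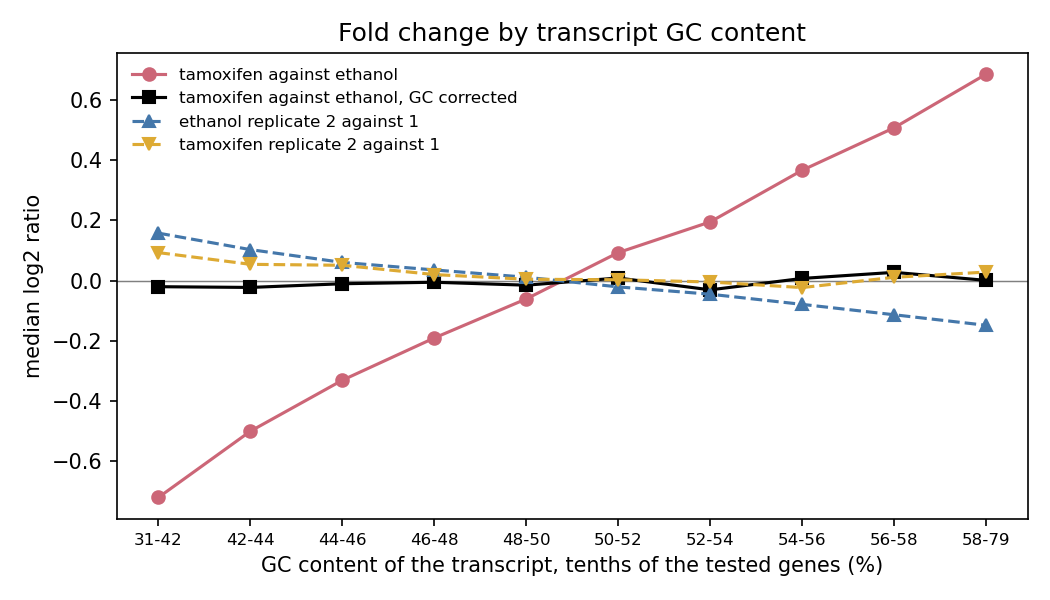
Median log2 ratio (vertical axis) in 10 groups of the tested genes ordered by transcript GC content in percent (horizontal axis), for tamoxifen against ethanol before and after GC correction and for the replicates of each group against each other. The uncorrected medians run from -0.72 to 0.69 and the corrected ones stay between -0.03 and 0.03.

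Among genes of core and naive pluripotency, 7 of 38 measured members rose and 8 fell (6 higher and 8 lower adjusted over the list alone). Pecam1, a surface marker of naive stem cells, fell 3.03-fold from 93.6 ± 7.15 to 30.9 ± 0.638 CPM (SD, n = 2), and the nuclear receptor gene Nr0b1 fell 4.66-fold. Rex2 fell by 1.46 log2 (-0.55 and no longer called with GC correction; it has close copies, so its count is uncertain), and Klf2 rose by 1.17 (0.42, not called with GC correction). The core factors Pou5f1 (0.18 ± 0.17, SE) and Sox2 (-0.12 ± 0.15) did not pass the test. With GC correction Pou5f1 turned to -0.35, not called, and it was called lower when ethanol replicate 1 was also left out (-0.55). Nanog had 0.37 ± 0.17 and passed with GC correction (0.64), with total counts (0.49) and without ethanol replicate 1 (0.49). Esrrb had -0.24 ± 0.15 and passed only with GC correction (-0.59), whereas Klf4 rose by 0.62 ± 0.14 and did not pass with it (0.29). The corrected calls of Nanog (0.49 and 0.79) and Esrrb (-0.68 and -0.50) ended without tamoxifen replicate 1 and without replicate 2. As a set the list did not stand apart from other genes (camera adjusted p = 0.710), and its median (0.03) and mean (-0.10) differed in sign. Without tamoxifen replicate 2, 4 members were higher, and with total counts 12.

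Of the genes of formative and primed pluripotency, which mark the epiblast after implantation, 8 of 25 rose and 2 fell (8 higher and 2 lower adjusted over the list alone). Fgf5 rose 2.73-fold, Sall2 2.70-fold and Zic2 2.60-fold, while Fgf15 fell 3.77-fold, from 14.3 ± 0.360 to 3.80 ± 0.624 CPM (SD, n = 2). With GC correction 4 higher and 4 lower were called, Zic2 at 0.74 log2, and the list did not stand apart in either test (camera adjusted p = 0.270 and 0.984). Without ethanol replicate 1, 5 members were lower.

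Receptors and targets of LIF and STAT3 signaling were higher with tamoxifen in 9 of 18 cases and lower in none (9 higher and 0 lower adjusted over the list alone). Myc rose 3.43-fold from 40.7 ± 13 to 139 ± 1.42 CPM (SD, n = 2), the kinase gene Pim1 2.31-fold, and Junb 2.61-fold (0.58 log2 with GC correction). The list was higher than other genes (camera adjusted p = 0.00130; 0.0398 with GC correction, where 6 were higher), a call lost with an estimated correlation (adjusted p = 0.579). The estimate (-0.0107) lay below the preset 0.01, and that form of the test has only 2 residual degrees of freedom. Here and for the lists below, where estimates reached 0.587 (mesendoderm), a call lost in it neither shows nor excludes that correlated members made the call. The corrected call was lost without ethanol replicate 2 (camera adjusted p = 0.0946) and without tamoxifen replicate 1 (0.103).

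Targets of FGF and ERK signaling rose in 13 of 25 cases and fell in 1 (13 higher and 2 lower adjusted over the list alone). This list shares Myc, Fos and Egr1 with the LIF list, so the results of these lists are not independent. Besides Myc, the immediate early gene Ier2 rose by 1.14 ± 0.16 log2 (SE; 0.43 with GC correction) and the feedback inhibitor Spry4 by 0.95 ± 0.14. Spred1, also an inhibitor of the pathway, fell by 0.97 (-0.38, not called with GC correction). The list was higher as a set (camera adjusted p = 0.00107, adjusted p = 0.579 with an estimated correlation), and 8 members were higher and 1 lower with GC correction (camera adjusted p = 0.00425). Without ethanol replicate 1, 2 members were lower, as with no filter on low counts.

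Nodal and BMP pathway genes moved both ways, 5 of 22 higher and 6 lower (5 higher and 7 lower adjusted over the list alone). Nodal rose 2.38-fold from 31.3 ± 3.98 to 74.6 ± 3.33 CPM (SD, n = 2) together with its antagonist Cer1, while Inhbb, an activin subunit gene, fell 3.30-fold (-2.44 log2 with GC correction) and the BMP receptor gene Bmpr1a fell by 0.83 log2 (-0.24, not called with GC correction). Of the WNT targets, 4 of 18 rose and 1 fell (3 higher and 0 lower adjusted over the list alone), among them the cyclin genes Ccnd2 (0.87 ± 0.14 log2, SE) and Ccnd1 (0.55 ± 0.15) and the WNT antagonist genes Notum (1.62 ± 0.30; 0.98 with GC correction) and Dkk1 (0.52 ± 0.18). Neither list stood apart from other genes (camera adjusted p = 0.994 and 0.281). Ccnd1 was not called without tamoxifen replicate 2 (0.50), and Dkk1 was not called without ethanol replicate 2 (0.42), tamoxifen replicate 1 (0.46) or tamoxifen replicate 2 (0.57) or by DESeq2 (0.51). Of the WNT targets, 2 were higher without tamoxifen replicate 2, and none was lower without it, without ethanol replicate 2 or with upper-quartile factors, total counts, DESeq2 or limma voom.

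Genes of the primitive endoderm, the extraembryonic lineage that forms the yolk sac, were higher in 13 of 30 cases and lower in 2 (14 higher and 2 lower adjusted over the list alone). Apoe rose 2.65-fold from 395 ± 62.4 to 1044 ± 118 CPM (SD, n = 2; 0.78 log2 with GC correction), the transcription factor gene Foxa2 2.62-fold and Thbd 2.21-fold, while the rise of the basement membrane collagen gene Col4a2 (0.84 ± 0.15 log2, SE) ended with GC correction (0.14). The list was higher as a set (camera adjusted p = 0.0136, adjusted p = 0.579 with an estimated correlation), and that call also ended with GC correction (camera adjusted p = 0.293; 6 members higher) and without ethanol replicate 2 (camera adjusted p = 0.123). Fibroblast markers were also higher (21 of 29). Members higher numbered 8 without tamoxifen replicate 1 and 7 without tamoxifen replicate 2, and 4 were lower without ethanol replicate 2.

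Mesendoderm genes, which mark the primitive streak and its descendants, rose in 7 of 18 cases and fell in 1 (7 higher and 1 lower adjusted over the list alone). With Cer1, the pioneer factor gene Foxa1 rose 4.02-fold (2.63 log2 without ethanol replicate 1, against 2.01), Lhx1 2.90-fold and Snai1, a repressor of epithelial genes, 2.86-fold (0.87 log2 with GC correction). The list was higher as a set (camera adjusted p = 0.00747; 0.0153 with GC correction, where 5 were higher and 0 lower), a call lost with an estimated correlation (adjusted p = 0.787) and without ethanol replicate 2 (camera adjusted p = 0.124). The corrected call was lost without ethanol replicate 2 (camera adjusted p = 0.316) and without tamoxifen replicate 1 (0.103). The rise came with that of fibroblast markers (21 of 29 higher). Members lower numbered 2 without ethanol replicate 2 and 0 without tamoxifen replicate 2.

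Neuroectoderm genes were split, 9 of 25 higher and 3 lower (9 higher and 3 lower adjusted over the list alone). Tubb3, a neuronal tubulin gene, rose by 1.0 ± 0.15 log2 (SE) and Sox9 by 2.53 ± 0.42 from 0.297 ± 0.0403 CPM (SD, n = 2), while the neuronal cytoskeleton genes Stmn2 (-1.08 ± 0.16) and Map2 (-1.20 ± 0.23) fell. Trophectoderm genes were higher in 10 of 24 cases and lower in 3 (11 higher and 3 lower adjusted over the list alone): Hand1 (1.25 ± 0.23), Eomes (0.74 ± 0.15) and Krt8 (0.80 ± 0.14; 0.31, not called with GC correction) rose, and Ascl2 fell 4.29-fold (-2.72 log2 with GC correction). With GC correction 5 higher and 4 lower were called in the first list and 4 higher and 5 lower in the second. Neither stood apart from other genes (camera adjusted p = 0.128 and 0.160), although the neuroectoderm list did without ethanol replicate 1 (0.0374; 14 higher and 5 lower) and without tamoxifen replicate 2 (0.0296), at the preset correlation (adjusted p = 0.787 with an estimated one and all libraries). Without ethanol replicate 2, 5 neuroectoderm genes were lower, and without either tamoxifen library 1 trophectoderm gene was.

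Hox genes, the homeobox genes that pattern the body axis, were higher with tamoxifen in 19 of 30 cases and lower in none (20 higher and 0 lower adjusted over the list alone). Fibroblast markers moved in the same direction (21 of 29 higher, 20 with GC correction). Levels of the Hox genes were low, and the most abundant, Hoxd13, averaged 10.9 ± 2.36 CPM with tamoxifen (SD, n = 2; named after its values were seen). Hoxd12 had no read in the ethanol libraries and 11 and 13 in the tamoxifen libraries, at least 10.4-fold higher against a floor of 3 counts over the ethanol group, which covers counting error only. Hoxd10 rose 5.06-fold, from 0.414 ± 0.151 to 2.01 ± 0.154 CPM (SD, n = 2), Hoxd9 3.53-fold (1.1 log2 with GC correction) and Hoxc6 2.24-fold. The corrected call of Hoxd9 ended without ethanol replicate 2 (0.78), tamoxifen replicate 1 (1.16) or tamoxifen replicate 2 (1.02). That of Hoxc6 ended without ethanol replicate 2 (0.73) or tamoxifen replicate 1 (0.68). As a set the genes were higher than others (camera adjusted p = 2.0e-05; 1.21e-06 with GC correction, where 10 were higher), a call lost with an estimated correlation (adjusted p = 0.678). DESeq2 called 6 of them, and 11 were higher without ethanol replicate 2, 8 without tamoxifen replicate 1 (where Hoxc6 was not called, at 0.85) and 10 without tamoxifen replicate 2.

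Genes of the two-cell-like state, a transient totipotent-like condition of some stem cells, rose in 7 of 12 cases and fell in none (8 higher and 0 lower adjusted over the list alone). Zscan4c rose 3.98-fold from 1.29 ± 0.199 to 5.08 ± 0.215 CPM (SD, n = 2), Zscan4b 4.40-fold, Zscan4d 3.78-fold and Usp17le 6.94-fold. These are multicopy families whose reads can be split between copies, so the values of single members are uncertain. Copies are also not independent members, in the count or in the set test. The estimated inter-gene correlation was 0.185 (0.222 with GC correction), against the preset 0.01. Of 30 genes on the list, 12 were measured. The set was higher than other genes (camera adjusted p = 0.00130; 3.23e-09 with GC correction, where 7 were higher), a call lost with an estimated correlation (adjusted p = 0.579).

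Among the other subunits of the BAF complexes, 7 of 27 rose and 3 fell (6 higher and 3 lower adjusted over the list alone). Bcl7a rose by 0.74 ± 0.16 log2 (SE) and remained called with GC correction (0.63), though not with it and without tamoxifen replicate 1 (0.55) or 2 (0.72), whereas the rises of Smarcc2 (0.60 ± 0.15; 0.29) and Gltscr1 (0.64 ± 0.16; 0.07) and the fall of Pbrm1 (-0.63 ± 0.15; -0.07), the defining subunit of PBAF, did not. ATPases of other remodelers gave 3 of 17 higher and 3 lower (2 higher and 3 lower adjusted over the list alone): Chd3 rose by 0.98 ± 0.15, and the falls of Atrx (-0.98 ± 0.15; -0.28), Smarca5 (-1.04 ± 0.17; -0.41) and Hells (-0.91 ± 0.17; -0.08) ended with GC correction. The corrected call of Chd3 (0.54) also ended without tamoxifen replicate 1 (0.59) or 2 (0.50). Neither list stood apart (camera adjusted p = 0.241 and 0.815), and the second had a median of 0.06 and a mean of -0.08. With GC correction 3 higher and 1 lower were called in the first list and 2 higher and 0 lower in the second. Without tamoxifen replicate 1, 2 BAF genes were higher and 1 lower (Pbrm1 at -0.57 and Gltscr1 at 0.59 not called), and 1 BAF gene was lower without tamoxifen replicate 2. Of the other ATPase genes 1 was higher without tamoxifen replicate 2 and 6 were lower without ethanol replicate 1.

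Polycomb subunit genes, whose products repress developmental genes through histone marks, rose in 9 of 30 cases and fell in 3 (9 higher and 3 lower adjusted over the list alone). Phc2 rose 2.62-fold from 21.0 ± 4.99 to 54.8 ± 0.00912 CPM (SD, n = 2; 0.71 log2 with GC correction) and Phf1 2.38-fold, while the fall of Pcgf5 (-0.91 ± 0.16 log2, SE) ended with GC correction (-0.27). The list did not stand apart (camera adjusted p = 0.281), but did with GC correction (camera adjusted p = 0.0168, adjusted p = 0.563 with an estimated correlation; 8 higher and 1 lower), though not without tamoxifen replicate 1 (camera adjusted p = 0.0575). By fry, which asks whether genes move on balance 1 way without comparing them with others, it was higher (adjusted p = 0.0320; 0.0844 with GC correction). Members lower numbered 7 without ethanol replicate 1, 1 without tamoxifen replicate 1 and 5 with no filter on low counts.

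Genes of cholesterol synthesis and uptake, in a list that also holds the fatty acid genes Scd1, Scd2 and Fasn, fell in 15 of 27 cases and rose in 3 (4 higher and 15 lower adjusted over the list alone). The list was fixed as one known to respond to tamoxifen-like compounds, and drug and deletion cannot be told apart here. The stearoyl-CoA desaturase gene Scd1 fell 2.74-fold from 337 ± 73.0 to 123 ± 18.7 CPM (SD, n = 2), the sterol oxidase gene Msmo1 2.56-fold and the sterol transporter gene Stard4 2.55-fold. The list was lower than other genes (camera adjusted p = 0.00107; 4.10e-07 with GC correction, where 13 were lower and none higher), a call lost with an estimated correlation (adjusted p = 0.579). By fry it was lower only without GC correction (adjusted p = 0.0320 and 0.0643 with it). With total counts 5 were higher.

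Stress and amino acid response genes, a list of targets of ATF4 and the unfolded protein response with some genes of the oxidative stress response, fell in 10 of 27 cases and rose in 4 (5 higher and 10 lower adjusted over the list alone). Psat1, an enzyme of serine synthesis, fell 2.41-fold from 505 ± 15.7 to 209 ± 27.2 CPM (SD, n = 2), Cth, which makes cysteine, 2.96-fold, and the quinone reductase gene Nqo1 1.82-fold, while Sesn2 rose 2.74-fold (0.87 log2 with GC correction). The list did not stand apart (camera adjusted p = 0.281), but was lower with GC correction (camera adjusted p = 0.0103, adjusted p = 0.678 with an estimated correlation; 4 higher and 11 lower), though not without ethanol replicate 2 (camera adjusted p = 0.0661). With total counts 7 were higher.

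p53 targets rose in 13 of 36 cases and fell in 8 (14 higher and 8 lower adjusted over the list alone). With Sesn2 and Ccnd2, the Notch ligand gene Jag2 rose by 1.41 ± 0.15 log2 (SE; 0.65 with GC correction) and Bbc3, which encodes the apoptosis activator PUMA, by 1.37 ± 0.17 (0.45). The list missed the threshold (camera adjusted p = 0.0771) and passed it with GC correction (camera adjusted p = 0.0103, adjusted p = 0.529 with an estimated correlation; 8 higher and 1 lower) and without ethanol replicate 2 (0.0404). By fry it was higher only with GC correction (adjusted p = 0.00362; 0.0764 without it). Without tamoxifen replicate 2, 7 were higher and 1 lower, and 2 were lower without tamoxifen replicate 1. Lower members numbered 4 with total counts and 5 with upper-quartile factors, and with no filter on low counts the list passed (camera adjusted p = 0.0378).

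Genes of the G2 and M phases fell in 19 of 32 cases and rose in 1 (1 higher and 20 lower adjusted over the list alone). The spindle genes Nusap1 (-1.01 ± 0.15 log2, SE), Cenpe (-0.96 ± 0.17) and Gas2l3 (-1.22 ± 0.16) remained called with GC correction, and Hmmr (-0.91 ± 0.16; -0.36) did not. The corrected calls ended without tamoxifen replicate 1 for Nusap1 (-0.53) and Cenpe (-0.33) and without tamoxifen replicate 2 for all 3 (Nusap1 -0.37, Cenpe -0.66, Gas2l3 -0.50). The set was lower than other genes (camera adjusted p = 3.46e-04; 0.0103 with GC correction, where 8 were lower and 0 higher), a call lost with an estimated correlation (adjusted p = 0.579). The corrected call was lost without tamoxifen replicate 1 (camera adjusted p = 0.0501). Without tamoxifen replicate 1, 7 members were lower, none was higher without it or without tamoxifen replicate 2, and 2 were with total counts. Replication genes showed no shared direction, 6 of 33 higher and 7 lower (6 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.976), with the DNA polymerase subunit gene Pold1 higher (1.34 ± 0.16; 0.63 with GC correction). Ccne2 (-1.39 ± 0.22; -0.49) and Slbp (-0.72 ± 0.15; -0.34) fell and Gins2 rose (0.63 ± 0.15; 0.38), calls that ended with GC correction, where 3 higher and 1 lower were called. Replication genes higher numbered 2 without tamoxifen replicate 2, and those lower 3 without tamoxifen replicate 1 and 4 with total counts.

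Markers of embryonic fibroblasts, cells on which stem cells are often grown, were higher with tamoxifen in 21 of 29 cases and lower in none (24 higher and 0 lower adjusted over the list alone). Acta2, smooth muscle actin, rose 2.38-fold from 150.3 ± 16.4 to 358 ± 7.0 CPM (SD, n = 2), the collagen genes Col6a1 3.67-fold and Col6a2 3.05-fold, and the secreted YAP target Cyr61 2.11-fold. The list was higher than other genes (camera adjusted p = 2.74e-10; 1.63e-14 with GC correction, where 20 were higher and 1 lower), a call lost with an estimated correlation (adjusted p = 0.579). The labels do not say whether feeder cells were present. Extracellular matrix and adhesion genes rose in 11 of 36 cases and fell in 2 (11 higher and 2 lower adjusted over the list alone): besides Cldn3, the integrin gene Itgb4 (1.19 ± 0.16 log2, SE; 0.53 with GC correction) and the laminin gene Lamb2 (1.17 ± 0.17; 0.57) rose and Itga1 fell (-1.60 ± 0.26). That list was higher (camera adjusted p = 0.0172, adjusted p = 0.579 with an estimated correlation), a call that ended with GC correction (camera adjusted p = 0.293; 10 higher and 4 lower), and 19 were higher with total counts.

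Among ribosomal protein genes 13 of 81 were higher and 18 lower (13 higher and 18 lower adjusted over the list alone). Besides Rpl22l1, Rps27a (-0.77 ± 0.16 log2, SE; -0.37, not called with GC correction) and Rps6 (-0.80 ± 0.17; -1.39 with GC correction) fell, and Rps4l rose (0.85 ± 0.18; 0.24, not called with GC correction); reads shared with pseudogenes make these values uncertain. Nuclear genes of oxidative phosphorylation were higher in 9 of 80 cases and lower in 16 (8 higher and 15 lower adjusted over the list alone), with Atp5j (-1.1 ± 0.16) and Cox6c (-0.88 ± 0.15) lower in both tests (the corrected call of Cox6c ended at -0.64 without tamoxifen replicate 1 and at -0.72 without replicate 2) and the calls of Atp5s (-0.83 ± 0.16; -0.18) and Atp5d (0.94 ± 0.17; 0.33) ended by GC correction. Neither list stood apart (camera adjusted p = 0.710 and 0.483), and with GC correction 5 higher and 11 lower and 4 higher and 14 lower were called. With total counts 9 ribosomal genes were lower and 14 phosphorylation genes higher, as were 14 with upper-quartile factors. Without tamoxifen replicate 2, 0 ribosomal genes were higher and 6 lower (Rps6 at -0.66 and Rps4l at 0.56 not called), and 4 and 8 phosphorylation genes. Without tamoxifen replicate 1, 8 ribosomal genes were lower. Phosphorylation genes higher numbered 16 without ethanol replicate 1, and those lower 30 without ethanol replicate 2 (camera adjusted p = 0.0264; adjusted p = 0.995 with an estimated correlation and all libraries).

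Histone genes, whose replication-dependent mRNAs lack a poly(A) tail and are poorly captured here, gave 3 of 33 higher and 2 lower (0 higher and 0 lower adjusted over the list alone), with 7 lower and 0 higher with GC correction. Hist3h2ba (-1.75 ± 0.44 log2, SE) and Hist2h2be (-0.84 ± 0.28) fell and Hist1h1c (1.26 ± 0.41) and Hist1h2bg (1.55 ± 0.52) rose, but GC correction ended the calls of Hist2h2be (-0.52), Hist1h1c (0.89) and Hist1h2bg (1.27), and reads shared between histone copies make all 4 values uncertain. Calls were also lost without ethanol replicate 2 (Hist3h2ba at -1.20, Hist1h2bg at 1.15, Hist2h2be at -0.75), without tamoxifen replicate 1 (Hist2h2be at -0.61) and without tamoxifen replicate 2 (Hist1h1c at 0.76, Hist1h2bg at 1.1). Histone genes higher numbered 5 without either ethanol library or tamoxifen replicate 1 and 0 without tamoxifen replicate 2, and 1 was lower without ethanol replicate 2 or tamoxifen replicate 1; without the latter the list was higher as a set (camera adjusted p = 0.0166). With GC correction it was lower as a set without ethanol replicate 1 (camera adjusted p = 0.00184) or tamoxifen replicate 2 (1.23e-04). These are calls at the preset correlation, and with an estimated one and all libraries the list was not called (adjusted p = 0.995, 0.814 with GC correction). DESeq2 called 0 higher and 1 lower, total counts 1 lower, and a stricter filter 1 higher (Hist2h2be at -0.71 not called with total counts, and Hist1h1c, Hist1h2bg and Hist2h2be not called by DESeq2). Genes used as references changed in 6 of 19 cases, 1 higher and 5 lower (1 higher and 5 lower adjusted over the list alone): Tfrc (-0.88 ± 0.18), Tbp (-1.06 ± 0.25) and Ipo8 (-0.57 ± 0.14) fell, and none of these 3 calls remained with GC correction (Tfrc -0.20, Tbp -0.58, Ipo8 -0.21), where 0 higher and 1 lower were called. Without either tamoxifen library 2 reference genes were lower and without ethanol replicate 1, as with total counts, 2 were higher, and Ipo8 was not called (-0.53 without replicate 1, -0.60 without replicate 2). With all libraries neither list stood apart (camera adjusted p = 0.397 and 0.483).

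**Figure D3:**
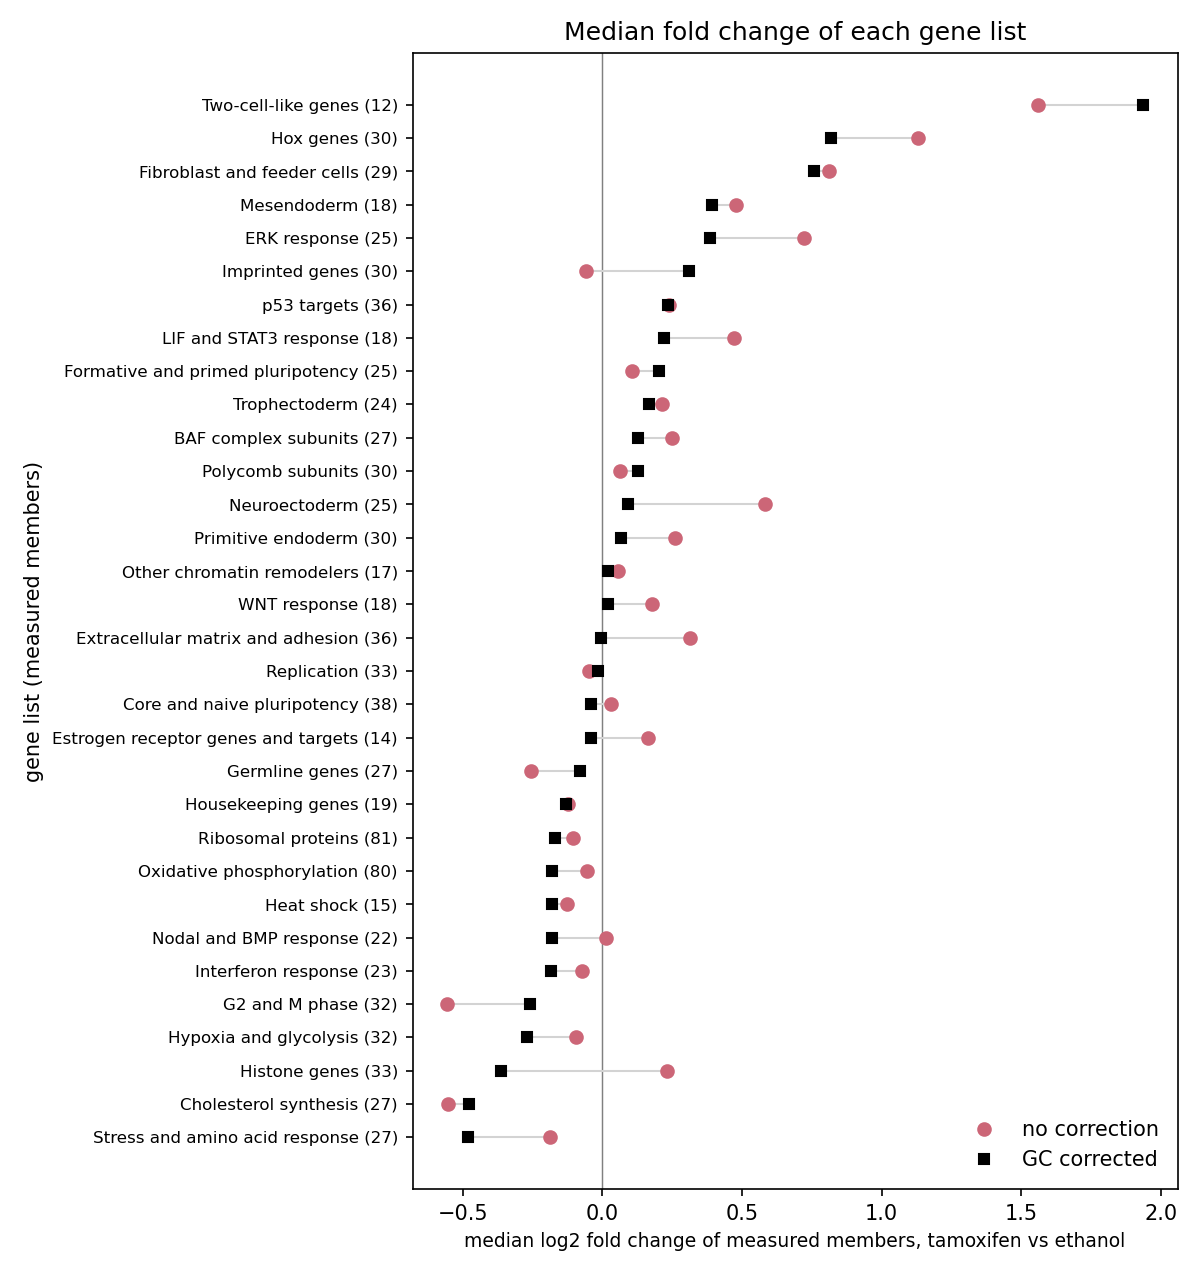
Median log2 fold change of tamoxifen against ethanol (horizontal axis) of the measured members of each gene list, with the number of members in parentheses, before GC correction (circles) and after it (squares). The two-cell-like genes (median 1.56 before and 1.93 after) and the Hox genes (1.13 and 0.82) lie highest, and the medians of the histone genes (0.23 and -0.36) and imprinted genes (-0.06 and 0.31) are among those that change sign with the correction.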

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

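The GC correction and the tests of GC bias, of reads outside genes and of both explanations for the fibroblast list were chosen only after the results were seen. Reads that HTSeq left unassigned because they overlapped more than 1 gene, which no comparison used, made up 1.05% of all counted reads in the tamoxifen libraries on average, above the 0.889 and 0.966% of the ethanol libraries. As a share of the reads in genes and on that line they were 1.68 and 1.61% with tamoxifen and 1.84 and 1.63% with ethanol, so the order did not hold on that scale.

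GC-rich transcripts were higher with tamoxifen and GC-poor ones lower, over 14395 genes. If GC-rich promoters were the source, the start of the transcript was predicted to carry the trend. The partial rank correlation across genes with GC of the first 200 nucleotides, given the rest, was 0.0113, and that with the rest, given the start, was 0.635. So the start did not carry it. This cannot decide about promoters, since the start came from each gene's longest transcript and holds no sequence upstream of it. For the share of reads outside genes, the ethanol pair differed by 11.0 percentage points, about as much as the group means (9.94). Its correlation with GC was -0.253, in the opposite direction. This cannot exclude that share as a source, since 1 pair of libraries may differ along GC for other reasons. GC bias of library preparation or sequencing stays open, since over 161 ribosomal protein and oxidative phosphorylation genes the slope was 0.434 ± 0.0696 (SE) log2 per 10 points of GC against 0.651 ± 0.00772 for other genes, -3.10 SE of the difference apart but far from flat. Bias that goes with the groups and an effect of the treatment on such transcripts cannot be told apart, since both divide the libraries in the same way.

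Fibroblast markers were higher with tamoxifen, and the GC trend was not their whole cause, because 20 of 29 members were higher with GC correction, 19 of them higher without it too. RNA of feeder fibroblasts may contribute and stays open: 9 members were not higher with GC correction, whose values ran from -0.52 to 1.68 over the list. Among the most abundant, Acta2 went from 150.3 to 358 CPM, Col1a1 from 66.4 to 182 and Fn1, which did not pass, from 1447 to 1779.9 (values named after they were seen). In ethanol 23 of the 29 members exceeded 10 CPM, so a high baseline would hide a small share of fibroblast RNA, 1 member stands in another list too, and no fibroblast library was analysed here. An effect of the treatment on these genes in the stem cells was not tested separately.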

How the results depend on the processing

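The GC corrections and their combinations were chosen only after the result was seen, and direction was compared only where a result was called in at least 1 of the 2 settings. Smarca4 was called as lower under each alternative, between -3.04 and -2.25 log2, and, when 1 library was left out, between -2.59 and -2.25 without GC correction and between -3.04 and -2.64 with it. The 6441 calls (3119 higher, 3322 lower) stayed within 1.5 times with RLE (6487), upper-quartile (6437) and total-count scaling (6602), with no filter (6819) or a stricter one (6266), with DESeq2 (5139) and with limma voom (6359). Leaving out 1 library gave 3975 to 7353 calls, 1835 to 3502 higher and 1991 to 3851 lower, the lowest of these without a tamoxifen library; the cause was not tested. Stricter thresholds call fewer genes by construction: 1829 at least 2-fold (859 higher, 970 lower) and 3806 at an adjusted p under 0.01 (1765 and 2041). GC correction gave 2977 (1435 and 1542) and, with length, 2864 (1394 and 1470). With GC correction there were 3740 calls (1858 and 1882) without ethanol replicate 1, 3623 (1523 and 2100) without ethanol replicate 2, 1300 (591 and 709) without tamoxifen replicate 1 and 812 (378 and 434) without tamoxifen replicate 2; the cause was not tested. The replicate number as a block gave 8087 calls (3919 higher, 4168 lower) and 4495 with GC correction, but the numbers are not stated to pair the libraries, and same-numbered libraries deviated with a correlation of 0.234 over only 2 pairs. The block called Nanog (0.37), changed the call of no other named gene and changed no camera call of a list without GC correction. Signs turned for Gltscr1 (-0.0068 with GC and length correction, -0.0061 with GC correction without ethanol replicate 2), Hells (0.045 in that last setting), Rps4l (-0.027 with GC correction without tamoxifen replicate 2), Atp5s (0.042 with GC correction without ethanol replicate 1) and Pou5f1 (-0.34 with the block and GC correction, -0.55 with GC correction without ethanol replicate 1). The histone list, not called with all libraries without GC correction, was called lower with GC correction together with the block (camera adjusted p = 0.0247), without ethanol replicate 1 (0.00184) or without tamoxifen replicate 2 (0.000123); the cause was not tested. With GC correction and 1 library left out, 3 more lists passed, at the preset correlation like the histone list, that did not with all libraries: BAF subunits without tamoxifen replicate 2 (camera adjusted p = 0.0408), ribosomal proteins without ethanol replicate 2 (0.00442) and oxidative phosphorylation without ethanol replicate 2 (4.05e-04) or tamoxifen replicate 2 (0.0435). In simulated data with 200 changed genes, none of the lowest in level, the test found 23.9% of 1.5-fold changes, so genes not called may still differ.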

Other observations

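The test of shared gene families and the GC correction were chosen only after results were seen. Imprinted genes went both ways, 6 of 30 higher and 8 lower (9 higher and 10 lower adjusted over the list alone): the maternally expressed noncoding RNA genes Meg3 (1.29 ± 0.17 log2, SE) and H19 (1.08 ± 0.15) rose, and Cdkn1c (-1.11 ± 0.15; -1.73 with GC correction) and the amino acid transporter gene Slc38a4 (-1.02 ± 0.16) fell (camera adjusted p = 0.960; median -0.06, mean 0.11). Without ethanol replicate 1, 10 were higher, and without tamoxifen replicate 1, 4 were lower; with total counts 12 were higher. Germline genes fell in 11 of 27 cases and rose in 3 (3 higher and 11 lower adjusted over the list alone), among them the meiotic chromosome genes Sycp3 (-1.89 ± 0.20; -0.87 with GC correction) and Sycp1 (-1.63 ± 0.25; -0.63, not called) and the receptor gene Kit (-1.36 ± 0.15), while Dmrtb1 rose (0.95 ± 0.19; 0.33, not called). That list missed the threshold (camera adjusted p = 0.0590) and passed with total counts (0.0480), with no filter (0.0356) and without ethanol replicate 1 (0.0290), tamoxifen replicate 1 (0.0474, with 1 higher and 6 lower) or tamoxifen replicate 2 (0.0300, with 1 higher), but with GC correction it gave 3 higher and 5 lower (camera adjusted p = 0.718). With an estimated correlation and all libraries it was not called (adjusted p = 0.579, 0.814 with GC correction).

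Hypoxia and glycolysis genes fell in 5 of 32 cases and rose in 4 (4 higher and 5 lower adjusted over the list alone): Ndrg1 (-1.49 ± 0.16 log2, SE) and the phosphofructokinase gene Pfkp (-1.19 ± 0.16) fell in both tests, and the calls of Ero1l (-0.75 ± 0.15; -0.18) and Bnip3 (-1.11 ± 0.22; -0.53) ended with GC correction. Corrected, Bnip3 was called lower without ethanol replicate 1 (-0.65), ethanol replicate 2 (-0.42) or tamoxifen replicate 1 (-0.95), but not without tamoxifen replicate 2 (-0.21). The list was lower only with GC correction (camera adjusted p = 0.0152, adjusted p = 0.643 with an estimated correlation; 0.483 without it), though not with it and without ethanol replicate 2 (camera adjusted p = 0.175), and 11 were lower without ethanol replicate 1 and 1 higher without tamoxifen replicate 2. Heat shock genes gave 4 of 15 higher and 7 lower (4 higher and 7 lower adjusted over the list alone), and the calls of Hspa1b (1.07 ± 0.19; 0.51) and Hspa1a (1.1 ± 0.21; 0.50), near-identical copies with uncertain counts, and of Hsp90aa1 (-0.86 ± 0.17; -0.44) and Bag3 (0.73 ± 0.16; 0.30) ended with GC correction, where 0 higher and 1 lower were called (camera adjusted p = 0.976 without it). Lower heat shock genes numbered 3 without ethanol replicate 2, 2 without tamoxifen replicate 1, 1 without tamoxifen replicate 2, 2 with total counts and 4 with upper-quartile factors.

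Interferon response genes were split, 5 of 23 higher and 6 lower (5 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.994), with Tap1 (1.11 ± 0.16 log2, SE), which loads antigen peptides, higher and Ddx58 (-0.74 ± 0.14), Oas1a (-2.69 ± 0.60) and Xaf1 (-1.30 ± 0.30) lower; without tamoxifen replicate 2, 2 were higher, and with DESeq2 3. Of the estrogen receptor genes and targets, 4 of 14 rose and 2 fell (4 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.483). Esrra (1.33 ± 0.20), Esr1 (0.81 ± 0.17), the gene of the estrogen receptor that tamoxifen binds, and Cyp1b1 (0.91 ± 0.24) rose, and Xbp1 fell (-0.50 ± 0.15), a call lost with total counts (-0.37) and without tamoxifen replicate 2 (-0.40). Lower members numbered 1 without tamoxifen replicate 1 and 0 without tamoxifen replicate 2, 0 with total counts and 1 with upper-quartile factors or DESeq2, and with GC correction 5 higher and 4 lower were called.

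The neighbours Lrrc34 and Lrriq4, both among the largest decreases, prompted a test of whether adjacent genes changed together. With GC correction and leaving out pairs whose symbols share their first 4 characters, 78 adjacent pairs both changed at least 2-fold in 1 direction (56 lower, 22 higher; 926 of 14395 ordered genes), against a median of 30 and at most 46 in 1000 orders permuted within chromosomes. Reads shared within gene families or by clone names do not account for the whole pattern, since 47 pairs without clone-like symbols or a shared first 3 letters remained, against a median of 27 and at most 41 in permuted orders. Examples chosen after their values were seen are Fam196b (-2.24) and Dock2 (-2.11), Slc28a1 (-1.81) and Pde8a (-1.98), and the imprinted Rian (1.44) and Mirg (2.61), in GC-corrected log2. Adjacent meant next in order among tested genes, at any distance. Some pairs share a gene, such as Meg3 with Rian and Rian with Mirg, so the 78 pairs are not all separate. Shared local regulation may link such neighbours, a hypothesis found and tested on the same data, and read-through transcription or overlap without strand was not tested.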
